A study of Mus musculus with 12 samples.

How the data were processed

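RNA of 12 samples was hybridised to Affymetrix mouse genome arrays, with 1 array per sample. The deposited table holds log2 expression values of 45101 probe sets, and RMA and Affymetrix Expression Console are the tools named, per the submitters' processing notes. Versions and further settings are not given in the sources used here. RMA corrects background, normalizes quantiles and summarises the probes of a set, so differences of dim probe sets are compressed. The 8 vesicle arrays had mean values of 6.10 to 6.11 and a maximum of 14.9, and the 4 cell line arrays had means of 5.76 to 5.82 and a maximum of 15.4. The sets therefore appear to have been normalized separately. A planned comparison of 2B1 cells with vesicles was not tested for that reason, and no level was set across the sets. Scanner files, detection calls and scan dates were not used here, so signal over background is unknown and batches of scanning were not tested.

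Per the labels, vesicles were freed of surrounding tissue with 1 mg/ml dispase, embryos were staged by somites, and each vesicle replicate pooled 4 to 8 vesicles. Cells of the 2B1 line were grown at 32 °C with gamma-interferon, transfected with a GFP vector with or without Dlx5, and kept at 37 °C without gamma-interferon for 4 days. Groups and replicate numbers were taken from the sample titles. No arrays held the same values, the highest share of equal values between a pair of arrays being 2.78%.

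Of the probe sets, 34958 were listed with 1 gene, 932 with several and 9211 with none. Those with several or none were left out of gene tests, and those with none were tested separately. Symbols were updated through a RefSeq gene table of the GRCm38.p6 assembly, which was also used for the chromosomes of genes. Of the symbols, 34754 were matched by gene identifier, 1 by accession and 203 were kept as listed, which gave 18194 genes. For the 9012 genes with more than 1 probe set, the set with the highest mean over the arrays of the fit was used. The lowest 25% of genes by that mean were left out, leaving 13645 genes in vesicles and 13647 in 2B1 cells.

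Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The labelled-null effect over both stages was fitted with stage as a covariate (8 arrays, 5 residual degrees of freedom). The E10 and E10.5 contrasts, their interaction and the wild-type stage contrast came from the means of the 4 vesicle groups (4 residual degrees of freedom), and the 2B1 contrast came from its 4 arrays (2 residual degrees of freedom). These contrasts therefore share arrays with each other, and the 2B1 contrast shares none with them. Gene lists with 4 or more tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 31 lists in vesicles and 32 in 2B1 cells. Calls of list members are given over all genes and adjusted over the list alone. The labelled-null and transfection effects were compared by a one-sided Fisher's exact test at an unadjusted p under 0.01 in each fit, with the numbers up and down held fixed, by correlations across genes, and by camera on the 100 genes with the lowest and the 100 with the highest moderated statistic, adjusted over these 2 sets. The plan named no adjustment for these 2 sets, and it was added after their unadjusted values were seen. The exact test was first run on a table that pooled both directions (p = 0.00191), and since that table ignored their unequal numbers, the test was replaced after its values were seen. The fry test of limma was run on each list as well.

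Named genes followed a rule. In each comparison they were Dlx5 and the other measured Dlx genes, and the 10 genes with the largest rise and the 10 with the largest fall past the threshold (5 each for stage). Where fewer than 10 passed in all, the 5 per direction with the smallest unadjusted p were added as values, among genes whose groups did not overlap and whose log2 difference was at least 0.5. Up to 4 members of each described list were named, those past the threshold first and then by size, and for opposite effects the 10 genes with the largest sum of sizes. List members beyond these 4, Atp10a and the sex-linked genes were chosen after their values were seen. Apart from the adjustment over the 2 sets of 100 genes and that form of the exact test, the tests of the comparisons, the lists and the rule were fixed before the data were examined. The tests on the Dlx5 probe set and some further runs, named below, were chosen after results were seen.

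The fits were tested on simulated data with the real means and residual spreads over 13645 genes, of which 176 to 197 were changed. For the effect over both stages limma called 71.7% of the changed genes at a log2 size of 1 and 94.3% at a size of 2. At E10 it called 18.8% and 86.8%, and at E10.5 27.8% and 81.5%. For the interaction it called 0% and 51.6%, for stage 0% and 86.4%, and for 2B1 cells 0% and 75.1%. The simulated noise was independent between genes, unlike the shared deviations of the E10 arrays, and the adjustment is stricter where fewer genes change. Except for stage, these shares may therefore be higher than the shares of real changes that the fits could call. For stage the real contrast called 296 genes, more than were changed in the simulation, so its shares may instead be too low.

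The alternatives were other filters, quantile normalization, median centring, the mean of all probe sets of a gene, probe sets tested singly, limma-trend, robust eBayes, array weights, a fit of all 12 arrays, the replicate number as a block, and each array left out in turn. Cyclic loess, covariates for Eif2s3y and for the spread of an array, the number as a block over all 4 groups for stage, the run without both E10 replicate 1 arrays and the run without the 2 arrays of narrow range were added after the data were seen, as were the runs of the gene lists with arrays left out or centred on their medians. Where leaving out an array leaves 1 in a group, that array is assumed to vary like those of the other groups.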

Results

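Gene expression was measured on 12 Affymetrix mouse genome arrays. Of these, 8 came from the otic vesicle, the epithelial sac that forms the inner ear, dissected at embryonic day 10 (E10) or at E10.5. At each stage there were 2 arrays of wild-type embryos and 2 of embryos labelled as lacking Dlx5, a homeobox transcription factor gene of the early otic epithelium. The other 4 arrays came from 2B1, a conditionally immortal otic vesicle cell line, with 2 cultures transfected with Dlx5 and 2 with an empty vector. Per the labels, each vesicle replicate is a separate pool of 4 to 8 vesicles, and the cell line replicates are independent cultures. The number of arrays, 2 per group, limits the precision. The series asks, by its title, which genes lie downstream of Dlx5 in the early inner ear.

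The Dlx5 probe set was higher, not lower, in the arrays labelled Dlx5-null. Its log2 level was 6.20 and 6.30 in the wild-type and 7.27 and 8.02 in the labelled-null arrays at E10, and 6.12 and 6.11 against 7.97 and 7.97 at E10.5. In 2B1 cells it was 5.14 and 4.80 after Dlx5 transfection and 4.66 and 4.79 with the empty vector, a difference of 0.25 (SE 0.18, limma adjusted p = 0.544). Where the probes lie relative to the deleted part of the gene or to the transfected sequence was not examined, since no probe sequence was used here, and a probe set outside them checks no label. Groups are therefore called by their labels throughout, and every direction below is that of the arrays as labelled. Dlx6, the neighbouring homeobox gene, lay between 4.61 and 5.16 in the vesicle arrays and was too dim to be tested.

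**Figure D1:**
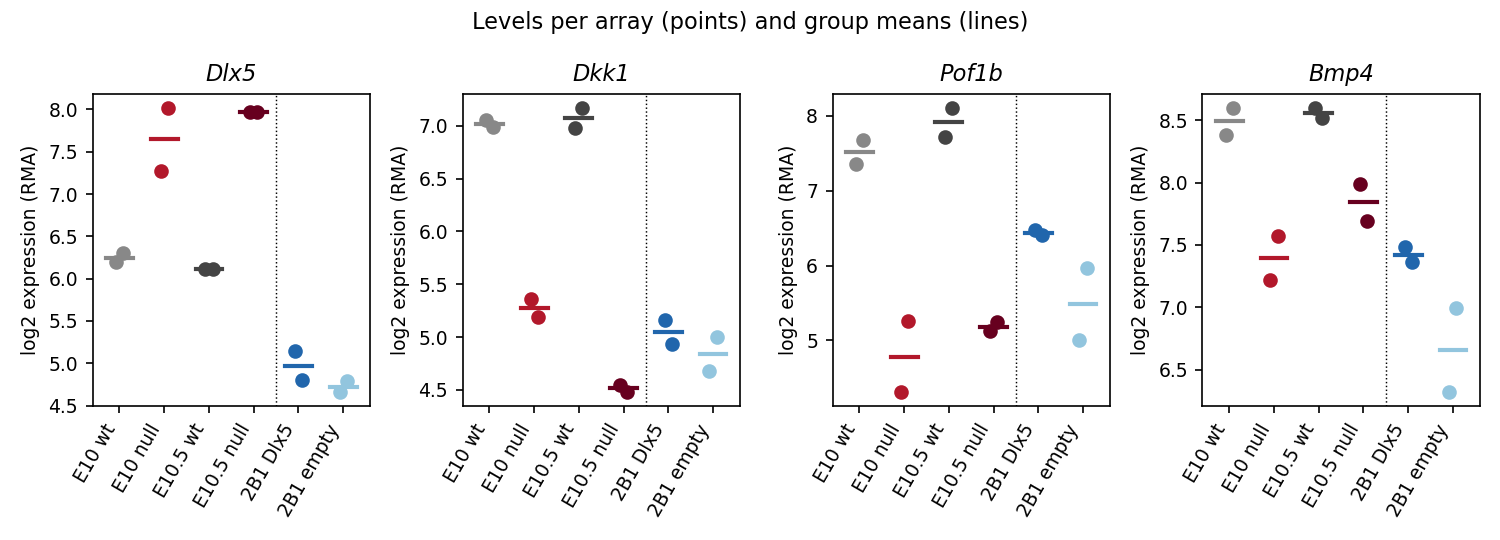
Log2 expression (vertical axes) of Dlx5, Dkk1, Pof1b and Bmp4 in the 6 groups (horizontal axes; wt, wild-type; null, labelled Dlx5-null), with a point per array and a line at the mean of 2 arrays. Dlx5 lay higher in the labelled-null than in the wild-type vesicle arrays; the 2B1 values right of the dotted line come from a separately normalized set and are not to be set against the vesicle values.

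Labelled Dlx5-null vesicles were compared with wild-type vesicles over both stages to find genes that depend on Dlx5 in the otic epithelium. Dkk1, which encodes a secreted Wnt antagonist, fell by 2.15 on the log2 scale in labelled-null vesicles (SE 0.17, 4 arrays a group, limma adjusted p = 0.00636), and its other probe set gave -1.80 (limma adjusted p = 0.0438 with probe sets tested singly). Pof1b, an X-linked gene for an actin-binding protein, fell by 2.73 (SE 0.21, limma adjusted p = 0.00636). Dlx5 itself rose by 1.63 (SE 0.18, limma adjusted p = 0.0475). The labelled-null values of each of these 3 genes lay on 1 side of the wild-type values of the same stage in 4 of 4 arrays. As groups by limma's camera test, genes of BMP signalling and of the dorsal otocyst fell, and genes of otic neurogenesis and of blood rose. None of these 4 lists passed when the correlation between genes was estimated (adjusted p = 0.425 for BMP, 0.688 for the dorsal otocyst, 0.351 for neurogenesis and 0.351 for blood).

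The list of BMP ligands, antagonists and response genes fell (16 of 18 lower, median -0.18, camera adjusted p = 6.80e-06 with a preset correlation of 0.01, adjusted p = 0.425 with an estimated correlation). Over all genes 0 of its members passed in limma (6 at an unadjusted p under 0.05), and adjusted over the list alone 4 fell and 1 rose. Those that fell were Bambi (-1.41, SE 0.28), a decoy receptor gene, Bmp4 (-0.91, SE 0.14), a ligand gene needed for canals and sensory patches, Msx1 (-0.70, SE 0.09), a BMP-responsive homeobox gene, and Fst (-0.70, SE 0.15), an antagonist gene. The ligand gene Bmp6 rose (0.86, SE 0.27). The dorsal otocyst and vestibular patterning list fell as well (11 of 16 lower, median -0.27, camera adjusted p = 0.00260, adjusted p = 0.688 with an estimated correlation), with 0 members past limma over all genes and 2, Bmp4 and Msx1, lower when adjusted over the list alone. Msx2 (-0.69, SE 0.24) and Otx1 (0.67, SE 0.57) passed neither test. The dorsal otocyst and BMP lists both hold Bmp4, Msx1, Msx2 and Bmper, so their falls are not independent of each other. Of 23 tested Wnt response genes and modulators, Dkk1 fell over all genes, and 3 fell when adjusted over the list alone, namely Dkk1, Dkk2 (-1.17, SE 0.17) and Znrf3 (-0.64, SE 0.16). The Wnt list did not pass (camera adjusted p = 0.0915).

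The otic neurogenesis and neurons list rose (20 of 25 higher, median 0.18, camera adjusted p = 0.000416, adjusted p = 0.351 with an estimated correlation). None of its members passed over all genes and 2 rose when adjusted over the list alone, the sensory neuron gene Pou4f1 (0.92, SE 0.17) and the microtubule-associated Dcx (0.65, SE 0.10). Elavl2 (-0.88, SE 0.30) and Gap43 (-0.57, SE 0.16) had lower values and passed neither test. Without wild-type E10 replicate 1 another probe set of Elavl2 was the brightest (-0.30), where the set used here was at -0.72. The blood list rose (9 of 9 higher, median 0.35, camera adjusted p = 4.74e-06, adjusted p = 0.351 with an estimated correlation), with no member past either test in limma and 1 at an unadjusted p under 0.05. Its largest differences were those of the red cell anion exchanger gene Slc4a1 (0.94, SE 0.48), the embryonic globin gene Hba-x (0.84, SE 0.47) and Alas2 (0.62, SE 0.24). At E10 the mean of the blood list was 7.55 and 8.06 in wild-type and 7.57 and 8.14 in labelled-null arrays. The rise therefore came mainly from E10.5. The cholesterol synthesis list fell (17 of 19 lower, median -0.16, camera adjusted p = 0.00117, adjusted p = 0.597 with an estimated correlation), with Fdps (-0.36, SE 0.11) and Sc5d (-0.30, SE 0.20) its largest differences and no member past either test. These 5 lists kept their calls with each of the 8 arrays left out in turn. The median of the BMP list was -0.08 without labelled-null E10 replicate 1 and -0.29 without labelled-null E10 replicate 2, that of the dorsal otocyst -0.14 without wild-type E10 replicate 2 and -0.09 without labelled-null E10 replicate 1, and that of cholesterol synthesis -0.26 without wild-type E10 replicate 1, -0.09 without wild-type E10 replicate 2 and -0.10 without labelled-null E10.5 replicate 2.

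The Dlx family passed camera (3 of 4 higher, median 0.17, camera adjusted p = 0.00303, adjusted p = 0.351 with an estimated correlation), with Dlx5 as its only member past limma, beside Dlx3 (0.24, SE 0.11), Dlx4 (0.10, SE 0.20) and Dlx1 (-0.20, SE 0.33). Without labelled-null E10 replicate 1 Dlx4 and Dlx1 turned to -0.03 and 0.20. Periotic mesenchyme (13 of 18 lower, median -0.17, adjusted p = 0.0219) and endothelium (10 of 13 lower, median -0.09, adjusted p = 0.0356) fell, and ion transport and otoconia of the inner ear rose (6 of 9 higher, median 0.14, adjusted p = 0.0317). With an estimated correlation these 3 lists had an adjusted p = 0.372, 0.351 and 0.425. Lum (-0.86, SE 0.28), Sox17 (-0.66, SE 0.21) and Gjb2 (0.64, SE 0.14) were examples, of which Gjb2 rose when adjusted over its list alone. The Dlx family call was lost without wild-type E10 replicate 1 (adjusted p = 0.0731). The periotic mesenchyme call was lost without wild-type E10 replicate 1 (0.0731), labelled-null E10 replicate 1 (0.0603), labelled-null E10 replicate 2 (0.0959) or wild-type E10.5 replicate 1 (0.0592). The call of endothelium was lost without wild-type E10 replicate 1 (0.330), labelled-null E10 replicate 2 (0.253), wild-type E10.5 replicate 1 (0.322), wild-type E10.5 replicate 2 (0.223), labelled-null E10.5 replicate 1 (0.447) or labelled-null E10.5 replicate 2 (0.0687). The call of ion transport was lost without wild-type E10 replicate 1 (0.0731), wild-type E10 replicate 2 (0.211), labelled-null E10 replicate 1 (0.0863) or labelled-null E10 replicate 2 (0.151). Where the calls held, the median of the Dlx family was 0.11 without wild-type E10 replicate 2 and 0.28 without labelled-null E10 replicate 2, that of periotic mesenchyme -0.09 without wild-type E10 replicate 2, and that of endothelium -0.16 without labelled-null E10 replicate 1.

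Among genes short of the threshold with the smallest p-values, higher values in labelled-null vesicles were found for the sialyltransferase gene St8sia6 (1.00, SE 0.12), AI504432 (0.95, SE 0.14), the amphiphysin gene Amph (0.54, SE 0.09), the LIM homeobox gene Lhx1 (1.46, SE 0.26) and Arfgef3 (0.98, SE 0.17). Lower values were found for the heparin-binding growth factor gene Ptn (-0.94, SE 0.12), the zinc finger transcription factor gene Sp8 (-0.84, SE 0.11), Msx1, Irs4 (-2.29, SE 0.31) and Dkk2. The limma adjusted p of these 10 genes ran from 0.0657 to 0.174. Some of their other probe sets gave a difference under 0.5 times as large or of the other sign, namely those of St8sia6 (0.03 and 1.08), AI504432 (0.41), Lhx1 (0.45), Ptn (0.21 and -0.77) and Irs4 (0.10).

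In all, limma called 3 of 13645 genes over both stages. At an unadjusted p under 0.05 there were 560, 173 higher and 387 lower (326 to 1096 with single arrays left out). That was 4.1% of the genes, and the shares below were 3.31% at E10, 2.95% at E10.5 and 1.97% for the interaction. Each is less than an unadjusted p under 0.05 passes on average where nothing differs. These counts therefore point to no wider set of changed genes. For stage the share was 22.5% and in 2B1 cells 12.9%. Dkk1 missed the threshold without wild-type E10.5 replicate 1 (adjusted p = 0.0641) or labelled-null E10.5 replicate 1 (0.0556). Pof1b missed it without the latter (0.0556). Dlx5 missed it without wild-type E10 replicate 1 (0.0755), wild-type E10 replicate 2 (0.120) or any 1 of the E10.5 arrays (wild-type 0.185 and 0.356, labelled-null 0.197 and 0.244). The count was 1 without wild-type E10.5 replicate 1, 0 without labelled-null E10.5 replicate 1 (limma, 518 at an unadjusted p under 0.05) and 10 without labelled-null E10 replicate 2. The Y-linked Eif2s3y averaged 1.22 higher in the labelled-null arrays, and with its level as a covariate 0 genes passed in limma (smallest adjusted p 0.0544, 1551 at an unadjusted p under 0.05). The differences of the 3 genes stayed close to the main ones in that fit, at -2.11 for Dkk1, -2.59 for Pof1b and 1.65 for Dlx5. With single arrays left out they ran over -2.27 to -2.03, -2.92 to -2.54 and 1.52 to 1.82 in the same order. Both E10 replicate 1 arrays, which had a narrower spread of values than the E10 replicate 2 arrays (SD 2.32 and 2.33 against 2.47 and 2.45), also had lower Xist (5.07 and 4.98 against 9.72 and 9.36). Without both 20 genes passed, the 3 named above among them.

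**Figure D2:**
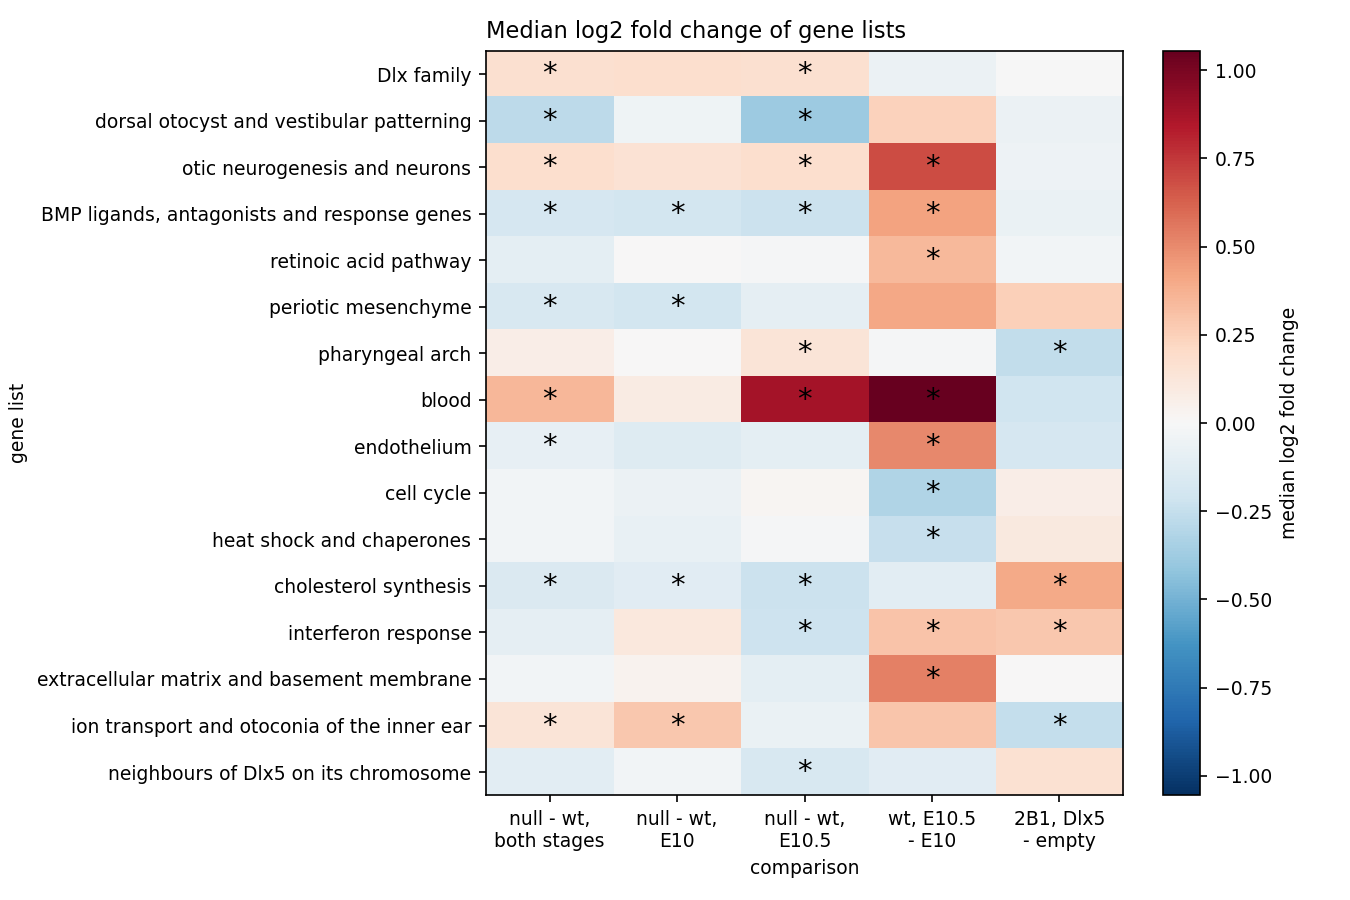
Median log2 fold change (colour scale) of the gene lists (vertical axis) in the comparisons (horizontal axis); asterisks mark a camera adjusted p under 0.05 with a preset correlation. The blood list reached 0.88 in labelled-null against wild-type vesicles at E10.5, where the dorsal otocyst list was at -0.38.

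At E10 alone, genes with lower values in labelled-null vesicles were Dkk1 (-1.75, SE 0.15), the keratin gene Krt23 (-2.70, SE 0.25), Pof1b (-2.74, SE 0.32), the hyaluronan link protein gene Hapln1 (-1.41, SE 0.16) and the muscle Z-disc gene Myot (-2.03, SE 0.25). Higher values were found for the blood cell signalling gene Was (1.33, SE 0.15) and for Vav3 (1.11, SE 0.17), Plekha4 (1.64, SE 0.20) and Eppin (1.20, SE 0.18). Gjb2, which encodes connexin 26, a gap junction protein of the cochlea, was higher as well (0.95, SE 0.15). None of these 10 passed, with limma adjusted p from 0.0759 to 0.340. Further probe sets disagreed in part for Vav3 (1.06 and -0.17), Plekha4 (1.05, 0.54 and 1.01) and Hapln1 (-0.90, -0.10 and -0.22). Dlx5 was higher by 1.40 (SE 0.24, limma adjusted p = 0.458), with Dlx3 at 0.35, Dlx1 at -0.47 and Dlx4 at 0.01. Without labelled-null E10 replicate 1 the last 2 turned to 0.40 and -0.38, and Dlx4 was at -0.32 without wild-type E10 replicate 2.

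The BMP list fell at E10 (12 of 18 lower, median -0.20, camera adjusted p = 0.00189, adjusted p = 0.779 with an estimated correlation), with 0 members past limma over all genes (5 at an unadjusted p under 0.05) and 2 lower when adjusted over the list alone, Bmp4 (-1.10, SE 0.19) and Msx1 (-0.70, SE 0.14). Bambi (-1.30, SE 0.43) and Bmp6 (1.21, SE 0.37) passed neither test. The ion transport and otoconia list rose (6 of 9 higher, median 0.29, camera adjusted p = 0.0125, adjusted p = 0.642 with an estimated correlation). Gjb2 rose when adjusted over the list alone and no member over all genes, with the otoconial protein gene Oc90 (0.70, SE 0.44) and the tectorial and otolithic membrane gene Otog (0.39, SE 0.15) passing neither test. Periotic mesenchyme (13 of 18 lower, median -0.20, camera adjusted p = 0.0364, adjusted p = 0.642 with an estimated correlation) and cholesterol synthesis (16 of 19 lower, median -0.12, camera adjusted p = 0.0376, adjusted p = 0.890 with an estimated correlation) fell, with Lum (-0.60, SE 0.41) and Msmo1 (-0.49, SE 0.20) as their largest differences and no member past either test. The otic neurogenesis list did not pass (camera adjusted p = 0.117), although Isl1 (1.08, SE 0.19) and Dcx (0.69, SE 0.16) rose and Elavl2 (-1.65, SE 0.23) fell when adjusted over the list alone.

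The E10 contrast gave 0 calls in limma and 451 genes at an unadjusted p under 0.05, 214 higher and 237 lower (256 to 1253 with single arrays left out), and 18 genes passed without both E10 replicate 1 arrays, where the BMP list was lost (adjusted p = 0.200). The BMP call was lost without wild-type E10 replicate 2 (0.115) or labelled-null E10 replicate 1 (0.481), with a median of 0.01 without the latter array. The call of ion transport was lost without wild-type E10 replicate 2 (0.368), labelled-null E10 replicate 1 (0.213) or labelled-null E10 replicate 2 (0.129). The call of periotic mesenchyme was lost without wild-type E10 replicate 1 (0.0665), wild-type E10 replicate 2 (0.299), labelled-null E10 replicate 1 (0.304) or labelled-null E10 replicate 2 (0.171). The call of cholesterol synthesis was lost without wild-type E10 replicate 2 (0.947), labelled-null E10 replicate 1 (0.287) or labelled-null E10 replicate 2 (0.258). Where the calls held, the median of the BMP list was -0.34 without wild-type E10 replicate 1 and -0.35 without labelled-null E10 replicate 2, and that of cholesterol synthesis -0.30 without wild-type E10 replicate 1.

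At E10.5, Dkk1 fell by 2.56 (SE 0.15, limma adjusted p = 0.00641), from 7.08 ± 0.13 in wild-type to 4.52 ± 0.05 in labelled-null vesicles (SD, n = 2). Its other probe set gave -1.72 and did not pass with probe sets tested singly (limma adjusted p = 0.437). At this stage Eif2s3y was at 3.21 and 3.45 in wild-type and 4.82 and 5.04 in labelled-null arrays. A part from the sex of the pools can therefore not be told apart from the label, here or in the interaction below. By camera the blood list rose and the interferon response, dorsal otocyst and BMP lists fell. With an estimated correlation the blood list passed (adjusted p = 0.0333) and the other 3 did not (0.238, 0.657 and 0.657). Lower values short of the threshold were those of Irs4 (-3.02, SE 0.29), the fatty acid oxidation gene Eci3 (-1.65, SE 0.17), the collagen gene Col5a3 (-1.74, SE 0.20), Pof1b (-2.73, SE 0.32) and Vwc2 (-1.59, SE 0.21). Higher values were those of Dlx5 (1.86, SE 0.24), the protease gene Ctse (1.50, SE 0.23), Pou4f1 (1.25, SE 0.19), AI504432 (1.14, SE 0.18) and the erythroid gene Hemgn (1.82, SE 0.30). The limma adjusted p of these 10 genes ran from 0.0831 to 0.376. The probe sets disagreed for Ctse (-0.28), AI504432 (0.36), Irs4 (0.01), Col5a3 (-0.02) and Vwc2 (0.14), with the difference of the set not used in parentheses.

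Blood genes were higher in 9 of 9 cases in labelled-null vesicles at E10.5 (median 0.88, camera adjusted p = 1.12e-14, adjusted p = 0.0333 with an estimated correlation). None rose over all genes, and 4 rose when adjusted over the list alone, the heme synthesis gene Alas2 (1.05, SE 0.28), the erythroid transcription factor genes Klf1 (0.96, SE 0.19) and Gata1 (0.85, SE 0.22), and the erythropoietin receptor gene Epor (0.54, SE 0.17). Blood is another tissue than the otic epithelium, and the mean of the list was 8.83 and 8.82 in the wild-type and 9.74 and 9.76 in the labelled-null arrays. The interferon response list fell (16 of 18 lower, median -0.22, camera adjusted p = 1.31e-06, adjusted p = 0.238 with an estimated correlation). None of its members fell over all genes, and 4 fell when adjusted over the list alone, namely Oas1a (-1.33, SE 0.20), Usp18 (-1.23, SE 0.19), Ifi35 (-0.65, SE 0.15) and H2-K1 (-0.60, SE 0.14). Another probe set of Ifi35 was the brightest without wild-type E10 replicate 1 or either labelled-null E10 array (-0.285), or wild-type E10.5 replicate 1 (-0.33). The set used here stayed at -0.655 to -0.645 there. Both lists kept their calls with each array left out in turn, the interferon response median being -0.34 without labelled-null E10.5 replicate 1.

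The dorsal otocyst list (14 of 16 lower, median -0.38, camera adjusted p = 2.84e-05, adjusted p = 0.657 with an estimated correlation) and the BMP list (15 of 18 lower, median -0.23, camera adjusted p = 0.000321, adjusted p = 0.657 with an estimated correlation) fell at E10.5. In both, the shared Msx1 (-0.70, SE 0.14) fell when adjusted over the list alone and no member over all genes. The shared Msx2 (-0.94, SE 0.34) and Bmp4 (-0.72, SE 0.19) and, in the BMP list alone, Bambi (-1.52, SE 0.43) passed neither test. The otic neurogenesis and neurons list rose (17 of 25 higher, median 0.18, camera adjusted p = 0.000321, adjusted p = 0.514 with an estimated correlation), Pou4f1 being its member past the test adjusted over the list alone. The Dlx family (4 of 4 higher, median 0.17, adjusted p = 0.00213) and pharyngeal arch (7 of 9 higher, median 0.14, adjusted p = 0.0221) rose by camera, while cholesterol synthesis (17 of 19 lower, median -0.23, adjusted p = 0.0221) and the neighbours of Dlx5 on its chromosome (17 of 20 lower, median -0.17, adjusted p = 0.0221) fell. With an estimated correlation these 4 lists had an adjusted p = 0.238, 0.657, 0.777 and 0.777. Examples were Pitx1 (0.36, SE 0.19), Sc5d (-0.41, SE 0.30) and the DNA replication gene Rpa3 (-1.10, SE 0.18), of which Rpa3 fell when adjusted over its list alone. Other Dlx genes were at 0.07 (Dlx1), 0.14 (Dlx3) and 0.20 (Dlx4). The neurogenesis call was lost without labelled-null E10.5 replicate 1 (adjusted p = 0.0819). The call of the pharyngeal arch was lost without labelled-null E10 replicate 1 (0.0678), wild-type E10.5 replicate 1 (0.167) or labelled-null E10.5 replicate 2 (0.434). The call of cholesterol synthesis was lost without labelled-null E10 replicate 1 (0.0713), wild-type E10.5 replicate 1 (0.104) or labelled-null E10.5 replicate 2 (0.305). The call of the neighbours of Dlx5 was lost without wild-type E10.5 replicate 1 (0.0617) or labelled-null E10.5 replicate 2 (0.269). Where the calls held, the median of the neurogenesis list was 0.11 without wild-type E10.5 replicate 2 and 0.28 without labelled-null E10.5 replicate 2, that of the pharyngeal arch 0.23 without labelled-null E10.5 replicate 1, and that of the neighbours of Dlx5 -0.27 without labelled-null E10.5 replicate 1.

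The E10.5 contrast gave 1 call and 403 genes at an unadjusted p under 0.05, 106 higher and 297 lower (153 to 550 with single arrays left out). Dkk1 missed the threshold without any 1 of the E10.5 arrays, while its difference stayed at -2.655 to -2.465. Its SE rose to 0.21 or 0.22 in these fits, which leave 1 array in a group. There were 4 genes that passed without labelled-null E10 replicate 1 and 4 without replicate 2, and 37 passed without both E10 replicate 1 arrays.

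**Figure D3:**
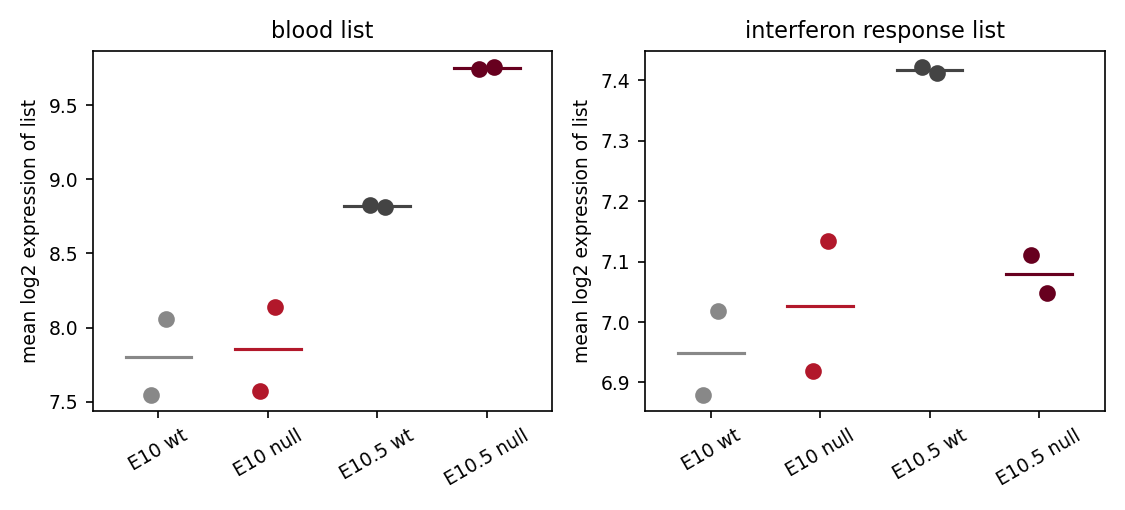
Mean log2 expression (vertical axes) of the blood and interferon response lists in the vesicle groups (horizontal axes; wt, wild-type; null, labelled Dlx5-null), with a point per array and a line at the mean of 2 arrays. At E10.5 the labelled-null arrays were at 9.74 and 9.76 for blood against 8.83 and 8.82 in wild-type arrays, and at 7.11 and 7.05 for interferon response against 7.42 and 7.41.

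Whether the labelled-null effect differed between E10 and E10.5 was tested as an interaction. The blood list was higher at E10.5 than at E10 in its labelled-null effect (9 of 9 higher, median 0.86, camera adjusted p = 1.30e-08, adjusted p = 0.0910 with an estimated correlation), and the interferon response list was lower (16 of 18 lower, median -0.37, camera adjusted p = 3.00e-06, adjusted p = 0.372 with an estimated correlation). Adjusted over the list alone, Klf1 (1.32, SE 0.27) passed in the first list and Usp18 (-1.36, SE 0.27) and Ifi35 (-1.31, SE 0.22) in the second, and no member of either over all genes. Genes with small p-values on the higher side were the carbonic anhydrase gene Car2 (1.17, SE 0.20), Hemgn (2.25, SE 0.42), Akap6 (1.30, SE 0.25) and Togaram1 (1.12, SE 0.23). On the lower side they were Eci3 (-1.69, SE 0.23), Plekha4 (-1.86, SE 0.28), Flot2 (-3.15, SE 0.54) and Col5a3 (-1.50, SE 0.28). Probe sets not used disagreed, in part or all, for Akap6 (0.57), Togaram1 (-0.20 and -0.01), Plekha4 (-1.26, -0.79 and -1.19), Flot2 (-0.86), Col5a3 (0.14) and Ifi35 (-0.37 and -0.17). The Dlx genes were at 0.46 (Dlx5), 0.53 (Dlx1), -0.22 (Dlx3) and 0.19 (Dlx4), Dlx1 turning to -0.33 without labelled-null E10 replicate 1, and Dlx4 to -0.14 without wild-type E10 replicate 1 and -0.20 without labelled-null E10 replicate 2. In limma 0 genes passed (smallest adjusted p 1) and 269 had an unadjusted p under 0.05, 75 higher and 194 lower (97 to 1163 with single arrays left out), while 3 passed without both E10 replicate 1 arrays. Another probe set of Ifi35 was the brightest without wild-type E10 replicate 1 or labelled-null E10 replicate 2 (0.04 for both), labelled-null E10 replicate 1 (-0.77) or wild-type E10.5 replicate 1 (-0.34), where the set used here stayed at -1.32 to -1.18. Both lists kept their calls with each array left out in turn, the interferon response median being -0.21 without wild-type E10 replicate 1 and -0.23 without labelled-null E10 replicate 2.

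Wild-type vesicles at E10.5 were compared with those at E10 to describe the step in development without the mutation. In these arrays Xist was at 5.07 and 9.72 at E10 and 9.17 and 9.01 at E10.5. Eif2s3y was at 7.04 and 3.96 at E10 and 3.21 and 3.45 at E10.5. A part from the sex of the pools can therefore not be told apart from stage. The largest rises past the threshold were those of the neurofilament gene Nefl by 4.16 (SE 0.66), the stathmin genes Stmn4 by 3.78 (SE 0.46) and Stmn2 by 2.87 (SE 0.42), Fabp3 by 2.84 (SE 0.49) and Apc2 by 2.68 (SE 0.46). Their limma adjusted p ran from 0.0291 to 0.0442. Without wild-type E10 replicates 1 and 2 in turn, Nefl was at 2.96 and 5.36, Stmn4 at 2.95 and 4.60, and Stmn2 at 2.22 and 3.51. Defa31 fell by 3.55 (SE 0.57), Krt23 fell by 2.85 (SE 0.25), Myo1h fell by 2.23 (SE 0.24), the RNA-binding protein gene Lin28a fell by 2.09 (SE 0.21) and Elavl2 fell by 2.06 (SE 0.23). The limma adjusted p of these 5 ran from 0.0190 to 0.0383. Among the probe sets not used, some disagreed with the one used for Nefl (1.54), Fabp3 (0.09), Apc2 (-0.19, 3.48 and -0.17) and Elavl2 (-1.06, -1.17, -0.40 and -0.71). Defa31 belongs to a family of near-identical defensin genes that 1 probe set can read together. Dlx5 (-0.14, SE 0.24), Dlx1 (0.10, SE 0.48), Dlx3 (0.02, SE 0.16) and Dlx4 (-0.35, SE 0.31) did not pass, Dlx1 being at -0.03 after quantile normalization and -0.04 after cyclic loess, and at -0.08 without wild-type E10 replicate 1.

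Of 25 otic neurogenesis and neuron genes 6 rose and 1 fell over all genes, and 14 rose and 2 fell when adjusted over the list alone (median 0.69, camera adjusted p = 0.00561, adjusted p = 0.577 with an estimated correlation). The LIM homeobox gene Isl1 (2.51, SE 0.19) and the tubulin gene Tubb3 (2.49, SE 0.40) were among those that rose. Of 25 extracellular matrix and basement membrane genes 0 rose and 1 fell over all genes, and 13 rose and 1 fell when adjusted over the list alone (median 0.54, camera adjusted p = 0.00428, adjusted p = 0.611 with an estimated correlation). Sparc (2.76, SE 0.87) and Mmp14 (1.74, SE 0.38) rose in the narrower test, and the proteoglycan gene Vcan (-1.14, SE 0.18) fell over all genes. In the retinoic acid pathway 2 of 13 genes rose over all genes, the retinaldehyde dehydrogenase gene Aldh1a3 (2.30, SE 0.43) and the retinol transporter gene Stra6 (1.45, SE 0.27), and 4 when adjusted over the list alone (median 0.35, camera adjusted p = 0.0167, adjusted p = 0.586 with an estimated correlation). Cell cycle genes fell as a list (23 of 29 lower, median -0.32, camera adjusted p = 3.39e-05, adjusted p = 0.586 with an estimated correlation). The spindle motor gene Kif11 (-1.25, SE 0.19) fell over all genes, and adjusted over the list alone 3 fell, with Cenpe (-0.89, SE 0.20) and Top2a (-0.69, SE 0.15) beside it.

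Endothelial genes rose as a list (12 of 13 higher, median 0.51, camera adjusted p = 0.0110, adjusted p = 0.577 with an estimated correlation), with 3 past limma over all genes and 6 adjusted over the list alone. The 3 were Tie1 (1.71, SE 0.21), Eng (1.18, SE 0.22) and Pecam1 (0.99, SE 0.16), Eng being at -0.36 after quantile normalization, and at -0.21 without wild-type E10.5 replicate 1, -0.17 without wild-type E10.5 replicate 2, -0.19 without labelled-null E10.5 replicate 1 and -0.19 without labelled-null E10.5 replicate 2, where another of its probe sets was the brightest. Blood genes rose as a list (9 of 9 higher, median 1.06, camera adjusted p = 0.0168, adjusted p = 0.577 with an estimated correlation), with 0 over all genes (5 at an unadjusted p under 0.05 in limma) and 5 adjusted over the list alone, Hba-x (2.60, SE 0.61) and Slc4a1 (1.99, SE 0.64) among them. The interferon response list rose (14 of 18 higher, median 0.30, camera adjusted p = 0.0144, adjusted p = 0.577 with an estimated correlation), with 3 over all genes, Usp18 (1.67, SE 0.19), Oas1a (1.39, SE 0.20) and Ifi35 (1.39, SE 0.15), and 5 adjusted over the list alone. Another probe set of Ifi35 was the brightest without wild-type E10.5 replicate 1 (0.48), wild-type E10 replicate 1 (1.30) or either labelled-null E10 array (1.705). The set used here stayed at 1.25 to 1.395 there. BMP genes rose as a list (15 of 18 higher, median 0.43, camera adjusted p = 0.0236, adjusted p = 0.785 with an estimated correlation), with 1 over all genes, Fst (1.24, SE 0.22), and 2 adjusted over the list alone. Heat shock and chaperone genes fell as a list (12 of 16 lower, median -0.25, camera adjusted p = 0.0270, adjusted p = 0.577 with an estimated correlation), with Hsph1 (-0.95, SE 0.17) past limma over all genes, and 4 lower and 2 higher when adjusted over the list alone. The endothelium call was lost without wild-type E10 replicate 2 (adjusted p = 0.128), wild-type E10.5 replicate 1 (0.0838) or labelled-null E10.5 replicate 1 (0.0721). The call of blood was lost without wild-type E10 replicate 2 (0.0989). The call of interferon response was lost without wild-type E10 replicate 2 (0.0989) or wild-type E10.5 replicate 1 (0.0770). The call of BMP was lost without wild-type E10 replicate 2 (0.0989). The call of heat shock was lost without wild-type E10 replicate 1 (0.217) or wild-type E10.5 replicate 1 (0.0622). Where the calls held, the median of the blood list was 0.66 without wild-type E10 replicate 1, and that of endothelium 0.32 without wild-type E10.5 replicate 2.

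Labelled-null arrays enter the stage contrast only through the residual spread, its degrees of freedom and the choice and filtering of probe sets. Leaving them out does not change the difference of a given probe set. The stage contrast called 296 genes in limma, 160 up and 136 down, with 3068 at an unadjusted p under 0.05. It called 0 genes without wild-type E10.5 replicate 1 (1306 at an unadjusted p under 0.05) or 2 (1442) and without labelled-null E10.5 replicate 1 (2480) or 2 (2486), 6 without wild-type E10 replicate 1, 873 without wild-type E10 replicate 2, 843 and 837 without labelled-null E10 replicates 1 and 2, and 1689 without both E10 replicate 1 arrays, 291 of them shared with the 296.

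**Figure D4:**
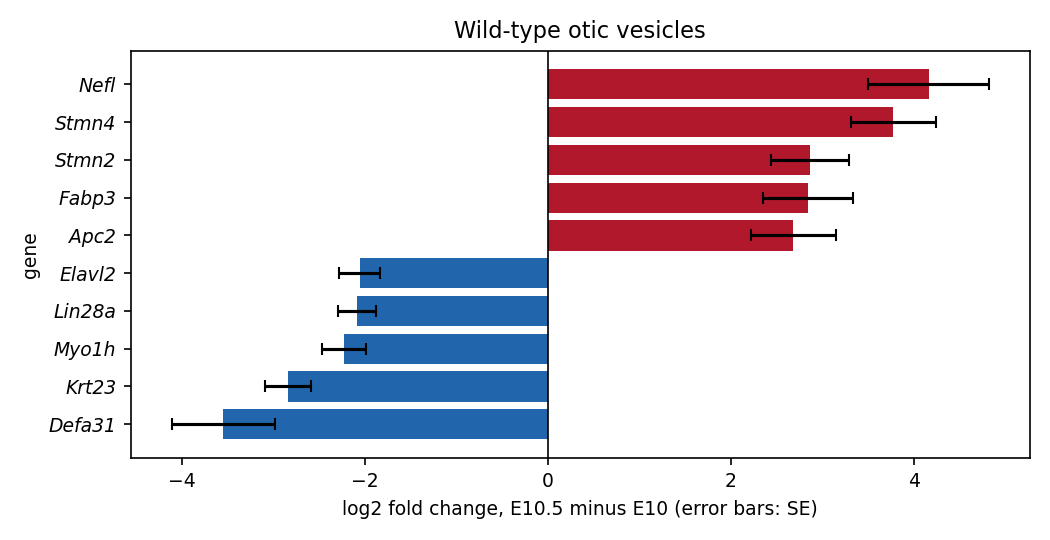
Log2 fold change (horizontal axis, E10.5 minus E10; error bars, SE) of the 5 genes with the largest rise and the 5 with the largest fall (vertical axis) among those past the threshold in wild-type vesicles. The values run from -3.55 for Defa31 to 4.16 for Nefl.

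In 2B1 cells, cultures transfected with Dlx5 were compared with cultures given the empty vector to find genes that respond to added Dlx5. By camera, cholesterol synthesis and interferon response genes rose as groups, and neither group passed with an estimated correlation (adjusted p = 0.969 and 0.969). Higher values were found for the cell cycle regulator gene Rgcc (1.27, SE 0.16), the protease inhibitor gene Serpinb1a (1.14, SE 0.16), Ptn (1.23, SE 0.18), the Wnt antagonist gene Apcdd1 (1.13, SE 0.16) and the collagen gene Col3a1 (1.06, SE 0.16). Lower values were found for the nestin gene Nes (-1.23, SE 0.16), Cpsf3 (-1.60, SE 0.22), Elp3 (-1.34, SE 0.20), Nsd2 (-0.98, SE 0.16) and Tnks2 (-1.02, SE 0.17). None of these 10 passed, with limma adjusted p from 0.324 to 0.332. Other probe sets disagreed, in part or all, with the one used for Ptn (-0.11 and 1.33), Nes (-0.05 and -0.26), Cpsf3 (0.24 and -0.33), Elp3 (-0.01 and -1.22), Nsd2 (-0.01, -0.09, -0.14 and 0.19) and Tnks2 (0.10 and 0.00). Those of Apcdd1 disagreed in part as well (0.89, -0.06, 0.20, 0.20 and 1.24). Dlx1 (0.18, SE 0.16), Dlx2 (-0.09, SE 0.19), Dlx3 (-0.40, SE 0.20) and Dlx4 (-0.01, SE 0.19) did not pass, Dlx4 turning to 0.04 after quantile normalization, 0.06 after cyclic loess and 0.03 after median centring. With single arrays left out it ran up to 0.20 and Dlx2 up to 0.09.

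Cholesterol synthesis genes rose as a list (17 of 20 higher, median 0.40, camera adjusted p = 0.00121, adjusted p = 0.969 with an estimated correlation), with 0 past limma over all genes and 5 adjusted over the list alone. Those were the sterol demethylase gene Cyp51 (0.90, SE 0.19), Msmo1 (0.82, SE 0.21), Ebp (0.76, SE 0.23), Sc5d (0.74, SE 0.21) and Fdft1 (0.72, SE 0.22). Interferon response genes rose as a list (25 of 26 higher, median 0.28, camera adjusted p = 0.00121, adjusted p = 0.969 with an estimated correlation), with 0 past limma over all genes or adjusted over the list alone and 8 at an unadjusted p under 0.05, Ifit1 (0.76, SE 0.24) and Usp18 (0.70, SE 0.22) among the largest. Per the labels the line was grown with gamma-interferon and kept without it for 4 days after transfection. Pharyngeal arch (7 of 9 lower, median -0.26, camera adjusted p = 0.0307, adjusted p = 0.969 with an estimated correlation) and ion transport and otoconia genes (8 of 9 lower, median -0.26, camera adjusted p = 0.0286, adjusted p = 0.969 with an estimated correlation) fell as lists, with Pitx1 (-0.69, SE 0.20) and Kcne1 (-0.40, SE 0.20) their largest differences and no member past either test. Periotic mesenchyme did not pass as a list (14 of 18 higher, median 0.25, adjusted p = 0.143 by camera), although Dcn (1.15, SE 0.25), Col3a1 (1.06, SE 0.16) and Postn (0.70, SE 0.19) rose when adjusted over the list alone. The BMP list did not pass (camera adjusted p = 0.693), Bmp4 being at 0.77 (SE 0.23). The pharyngeal arch call was lost without Dlx5-transfected replicate 1 (adjusted p = 0.0570) or empty vector replicate 1 (0.680). The call of ion transport was lost without Dlx5-transfected replicate 2 (0.177), empty vector replicate 1 (0.257) or empty vector replicate 2 (0.129). The median of the cholesterol synthesis list was 0.16 without empty vector replicate 1 and 0.67 without empty vector replicate 2, and that of interferon response 0.17 without empty vector replicate 1, where both lists kept their calls.

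In limma 0 of 13647 genes passed in 2B1 cells, with 1760 at an unadjusted p under 0.05, 1325 higher and 435 lower. With single arrays left out the 1760 became 420 to 6323. There were 4 calls without Dlx5-transfected replicate 1 and 11 without replicate 2, in fits that gave every gene the same variance. Empty vector replicate 1 had the narrowest spread of values (SD 2.19 against 2.29 to 2.31).

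The labelled-null and transfection effects share no array and were compared over 12572 genes tested in both. At an unadjusted p under 0.01 in each, 6 genes were lower in labelled-null vesicles and higher in Dlx5-transfected cells, where independent lists would share 1.39. Of genes that went the other opposite way there were 0, where 0.175 would be shared. With the labelled-null value first, the 6 were Ptn (-0.94 and 1.23), Apcdd1 (-0.95 and 1.13), the proteoglycan gene Dcn (-0.40 and 1.15), the growth cone gene Gap43 (-0.57 and 0.96), the hedgehog co-receptor gene Gas1 (-0.48 and 0.67) and Ing3 (-0.42 and 0.68). Apcdd1 was read by a different probe set in each fit, and the set used in vesicles gave 1.24 in 2B1 cells. Sets not used gave other differences in part for Apcdd1 (-0.96, -0.65, -0.15, 0.19 and -0.99 in vesicles; 0.89, -0.06, 0.20, 0.20 and 1.24 in 2B1 cells) and Ing3 (-0.12, -0.11 and 0.19; 0.44, 0.71 and 0.13). Those of Dcn (-0.20; -0.11) and Ptn (0.21 and -0.77; -0.11 and 1.33) differed in part as well. Fisher's exact test, one-sided and with the numbers up and down in each fit held fixed, gave p = 0.00491 for the 6 opposite genes, where 1.57 would be shared. In the same direction there was 1 gene, Atp10a (-0.83 and -1.07), where 1.01 would be shared. At an unadjusted p under 0.05 there were 67 opposite genes where 34.8 would be shared, and 13 in the same direction where 23.2 would be shared. No gene passed an adjusted p of 0.05 in both limma fits. Genes are not independent replicates, so the p overstates the certainty. The overlap was lost without labelled-null E10 replicate 1 (3 genes where 1.40 would be shared, Fisher's exact p = 0.166), wild-type E10.5 replicate 1 (3 genes where 0.858 would be shared, Fisher's exact p = 0.0544), wild-type E10.5 replicate 2 (2 genes where 0.897 would be shared, Fisher's exact p = 0.226) or 2B1 empty vector replicate 2 (16 genes where 14.7 would be shared, Fisher's exact p = 0.393). There were 10 opposite genes without wild-type E10 replicate 1, where 2.80 would be shared (Fisher's exact p = 0.000526).

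Across these genes the log2 fold changes had Pearson's r of -0.228 and Spearman's rho of -0.273, a description across genes that are not independent replicates. Pearson's r was -0.0835 without wild-type E10 replicate 2, -0.138 without labelled-null E10 replicate 1, -0.121 without labelled-null E10.5 replicate 2 and -0.126 without 2B1 empty vector replicate 1. Of the 100 genes with the lowest moderated statistic in labelled-null vesicles 76 were tested in 2B1 cells. As a set they did not pass there (43 higher, limma's camera adjusted p = 0.486 over the 2 sets). Of the 100 with the highest statistic 74 were tested. As a set they did not pass either (34 higher, median -0.03, camera adjusted p = 0.0735, unadjusted 0.0367, and adjusted p = 0.614 with an estimated correlation). They passed without wild-type E10 replicate 1 (0.0155), wild-type E10 replicate 2 (0.0493), labelled-null E10 replicate 2 (0.0391), labelled-null E10.5 replicate 1 (0.00544), 2B1 Dlx5-transfected replicate 1 (0.0434) or 2B1 empty vector replicate 2 (0.0289). The lowest genes passed without labelled-null E10.5 replicate 1 (0.00544).

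**Figure D5:**
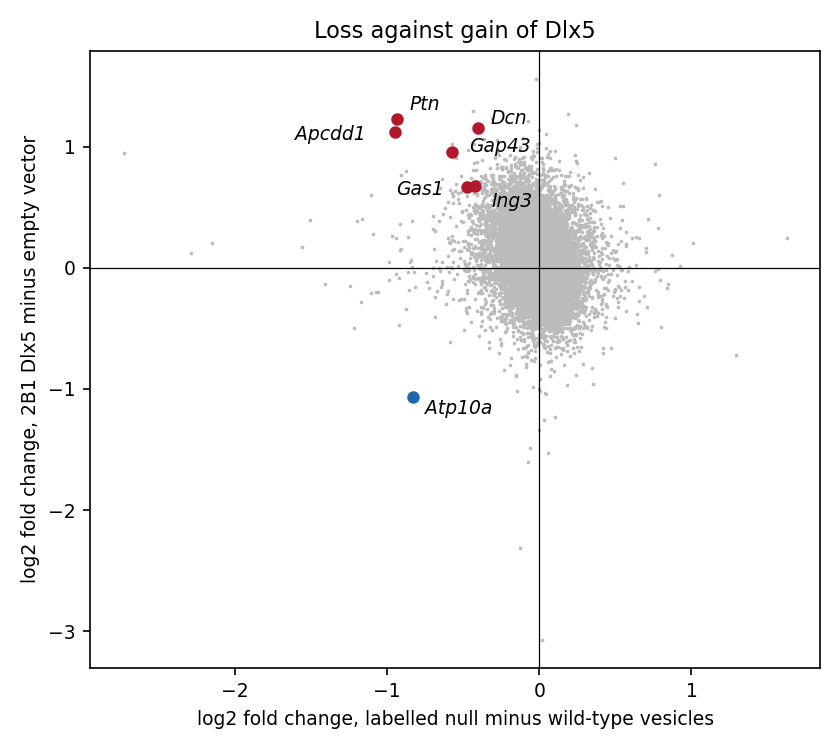
Log2 fold change of labelled-null minus wild-type vesicles over both stages (horizontal axis) and of Dlx5-transfected minus empty vector 2B1 cells (vertical axis), with a point for each of 12572 genes. The coloured points are the 6 genes with opposite directions and the 1 with the same direction at an unadjusted p under 0.01 in both.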

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

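The tests on the Dlx5 probe set, the runs with cyclic loess and without the 2 arrays of narrow range, the form of Fisher's exact test used, and the rules that left opposite dependence on Dlx5 and chance open were chosen only after the result was seen.

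The Dlx5 probe set was higher by 1.63 (SE 0.18) in the arrays labelled Dlx5-null. Signal from other Dlx genes stays open: the highest difference among 8 other Dlx probe sets was 0.27, but 5 of them were too dim to be tested and could hide a rise. Swapped genotype labels stay open: without the 2 arrays of narrow range the overlap with the transfection effect was in opposite directions (Fisher's exact p = 0.00168), but Dlx5 itself differed by 0.25 (SE 0.18) in 2B1 cells, so that those cells give no sure direction either. The same small 2B1 difference leaves open that the probe set reads a part of the transcript that the null allele may keep and the vector may lack. The position of the probes, which would tell these apart, was not used here, and a rise of the mutant transcript was not tested.

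The labelled-null and transfection effects correlated negatively across genes (r -0.228). Labelled-null E10.5 replicate 2 (SD 2.38) and 2B1 empty vector replicate 1 (SD 2.19) had the narrowest range of their own stage or line, and without both r was -0.107, so a part from range cannot be told apart from a part from Dlx5. Opposite dependence on Dlx5 stays open too. In the run without both arrays Dcn and Ing3 were no longer among the opposite genes, and Cp was new. Without both arrays the overlap remained (5 genes where 0.858 would be shared, Fisher's exact p = 0.00168), but this run repeats, on 10 of the 12 arrays, an overlap seen before. The hypothesis assumes the genotype labels, and the overlap was lost without labelled-null E10 replicate 1 (Fisher's exact p = 0.166), wild-type E10.5 replicate 1 (p = 0.0544) or 2 (p = 0.226), or 2B1 empty vector replicate 2 (p = 0.393).

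At E10 the replicate 1 arrays of both genotypes deviated from replicate 2 in the same genes (correlation across genes 0.707). A narrow range that follows the signal level of a gene is argued against as the whole cause, since the correlation was 0.651 after cyclic loess. Loess removes only such a trend, so a narrowing that differs between genes of like level was not tested. Without X- and Y-linked genes the correlation was 0.706 over 13215 genes, so these genes themselves did not carry it. That run keeps most genes and cannot tell whether the sex of the pools acted on others. A part from sex stays open, since Xist was 5.07 and 4.98 in these arrays and at least 8.91 in the other vesicle arrays. An earlier developmental point of these pools may account for a part, which stays open. Labelled-null replicate 2 minus 1 correlated at 0.246 with wild-type E10.5 minus wild-type E10 replicate 2, too little to decide. What the replicate 2 arrays share enters both differences with opposite signs and can lower that correlation. A shared day of dissection or hybridisation, which no label gives, was not tested.

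Of 34 splits of the 8 vesicle arrays into 4 and 4 that could be fitted with stage, 3, the real split among them, gave 3 or more genes over both stages, which is the number of the real split. The other 2 (with up to 24 genes) were among 6 splits that set both E10 replicate 1 arrays against both replicate 2 arrays, which deviated together, and the 27 further splits gave 0 genes. The other splits with genes are thus not free of structure, so that chance is neither supported nor excluded for that count.

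The labelled-null effect on the blood list differed between the stages, with a median of 0.86 at E10.5 minus E10 (camera adjusted p = 1.30e-08, adjusted p = 0.0910 with an estimated correlation). That on the interferon response list differed as well, with a median of -0.37 (camera adjusted p = 3.00e-06, adjusted p = 0.372 with an estimated correlation). Outside the gene tests, among 6909 probe sets with no gene listed, 1 was lower in labelled-null arrays at E10 (limma, 135 at an unadjusted p under 0.05). These 135 are fewer than that threshold passes on average where nothing differs. In the wild-type stage contrast 35 such probe sets passed in limma, 9 up and 26 down.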

How the results depend on the processing

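The runs with cyclic loess, without both E10 replicate 1 arrays, without the 2 arrays of narrow range, with Eif2s3y or array spread as a covariate and with the crossed pairing were chosen after seeing the data, as were the runs of the gene lists with arrays left out or centred. Over all alternatives, 190 values of the comparisons were scored as the same, 48 as stronger and 36 as weaker. A further 11 counts of opposite genes or correlations moved without crossing a threshold. Counts and correlations were given a fixed tolerance. Those scored as the same therefore include changes such as 3 to 2 genes over both stages after median centring. A score of stronger means a count above that tolerance or a threshold passed. For named genes 3352 values kept their direction and their side of the threshold, 243 came to pass it, 166 came to miss it and 36 turned direction. The small number of arrays and unknown signal over background limit what can be told, and the planned comparison of 2B1 cells with vesicles was not run because the sets appear separately normalized. Except where fewer genes or arrays in a run show it, the cause was not tested.

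Over both stages 3 genes passed in limma. Their number was 0 with the lower 50% of genes left out, 6 after quantile normalization, 6 after cyclic loess and 9 with limma-trend. It was 105 with array weights, 28 with all 12 arrays, 20 without both E10 replicate 1 arrays, 0 with Eif2s3y and 57 with array spread as a covariate. Single arrays left out gave 0 to 10. The adjusted p of Dlx5 was 0.0609 with the lower 50% of genes left out, 0.0707 after median centring, 0.0570 with robust eBayes, 0.0643 from the mean of the stage contrasts and 0.121 with Eif2s3y as a covariate. Those of Dkk1 and Pof1b were 0.0544 with Eif2s3y as a covariate, where their differences (-2.11 and -2.59) hardly moved, and that of Dkk1 at E10.5 was 0.0626 with the mean of probe sets.

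At E10 the count of 0 became 2 after quantile normalization, 2 after cyclic loess, 6 with all 12 arrays and 18 without both E10 replicate 1 arrays. At E10.5 the count of 1 became 0 with the lower 50% of genes left out, 3 after median centring, 0 with the mean of probe sets and 2 with limma-trend. It was 135 with array weights, 9 with all 12 arrays, 2 after cyclic loess and 37 without both E10 replicate 1 arrays, and 0 to 4 with single arrays left out. The interaction went from 0 to 3 without both E10 replicate 1 arrays.

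For stage the 296 became 999 after quantile normalization, 1099 after cyclic loess and 35 after median centring. It was 653 with limma-trend, 188 with robust eBayes, 1075 with all 12 arrays and 1689 without both E10 replicate 1 arrays, and 0 to 873 with single arrays left out. In 2B1 cells the 0 became 25 with limma-trend and 0 to 11 with single arrays left out.

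With the replicate number as a block the count was 18 over both stages, 11 at E10.5 and 258 in 2B1 cells, the last from a fit that gave all genes the same variance. The deviations of arrays with the same number correlated at 0.707 at E10, 0.0673 at E10.5 and -0.128 in 2B1 cells, and nothing in the labels ties the numbers across groups, so no pairing by number was assumed. The crossed pairing of the 2B1 numbers gave 20 genes. For stage, where the planned block within stage cannot be fitted, the number as a block over all 4 vesicle groups, chosen after seeing the data, gave 115 genes, 112 of them shared with the 296.

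The number of lists past camera fell with an estimated correlation to 0 from 9 over both stages, to 0 from 4 at E10, and to 1 from 9 at E10.5. It fell to 0 from 2 for the interaction, to 0 from 9 for stage and to 0 from 4 in 2B1 cells. By limma's fry, which tests whether the genes of a list move 1 way, 1, 0, 2, 0, 4 and 0 of these lists passed in the same order. The number past camera was 5 for the interaction and 2 in 2B1 cells with no filter, 2 in 2B1 cells after quantile normalization and 2 after cyclic loess. Without both E10 replicate 1 arrays it was 2 at E10 and 6 for the interaction. Single arrays left out gave 0 to 4 lists at E10, 2 to 4 for the interaction and 2 to 5 in 2B1 cells.

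Among lists past camera, quantile normalization ended the calls (adjusted p) of endothelium (0.245) and ion transport (0.110) over both stages, cholesterol synthesis (0.0816) at E10, the pharyngeal arch (0.114), cholesterol synthesis (0.0776) and the neighbours of Dlx5 (0.0544) at E10.5, endothelium (0.0654) for stage, the pharyngeal arch (0.182) and ion transport (0.182) in 2B1 cells. Cyclic loess ended those of ion transport (0.107) over both stages, cholesterol synthesis (0.0687) at E10, the pharyngeal arch (0.131), cholesterol synthesis (0.0855) and the neighbours of Dlx5 (0.0748) at E10.5, the pharyngeal arch (0.185) and ion transport (0.185) in 2B1 cells. With no filter those of periotic mesenchyme (0.0836) at E10, heat shock (0.0641) and interferon response (0.0641) for stage, the pharyngeal arch (0.149) and ion transport (0.170) in 2B1 cells were lost. Without both E10 replicate 1 arrays those of periotic mesenchyme (0.0532), endothelium (0.0699) and ion transport (0.0915) over both stages, BMP (0.200) and periotic mesenchyme (0.0818) at E10, the neighbours of Dlx5 (0.0710) at E10.5, heat shock (0.182) for stage were lost.

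The opposite genes, 6 in number, were 11 after quantile normalization, 11 after cyclic loess, 67 at an unadjusted p under 0.05 and 2 to 16 with single arrays left out, where Fisher's exact p ran up to 0.393. The correlation was -0.128 with the E10 contrast alone, -0.107 without the 2 arrays of narrow range and -0.312 to -0.0835 with single arrays left out. The set of highest genes passed in 2B1 cells with 50 genes (camera adjusted p = 0.00396), and its adjusted p ran over 0.00544 to 0.530 with single arrays left out. That of the set of lowest genes ran over 0.00544 to 0.758.

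Without both E10 replicate 1 arrays the direction of Dlx1 turned (0.12 over both stages, 0.22 at E10, -0.16 for the interaction, -0.080 for stage). For stage it turned after quantile normalization (-0.034) and cyclic loess (-0.040). Dlx4 turned over both stages with Eif2s3y (-0.19) or array spread (-0.022) as a covariate and at E10 without both replicate 1 arrays (-0.050). It turned in 2B1 cells after quantile normalization (0.036), median centring (0.030) and cyclic loess (0.055). Another probe set became the brightest for Eng in stage after quantile normalization (-0.36) and in 2B1 cells with all 12 arrays for Pdgfrb (-0.0050) and Tnks2 (0.095). With single arrays left out Dlx1 ran over -0.49 to 0.20 over both stages, -1.33 to 0.40 at E10, -0.33 to 1.39 for the interaction and -0.080 to 0.27 for stage. Dlx4 ran over -0.033 to 0.28, -0.38 to 0.40 and -0.20 to 0.57 in the first 3 of these and -0.21 to 0.20 in 2B1 cells. Dlx3 ran over -0.010 to 0.040 and Eng over -0.21 to 1.43 for stage, Ifi35 over -1.45 to 0.040 for the interaction and Dlx2 over -0.27 to 0.090 in 2B1 cells. The turns of Eng and Ifi35 came with another probe set as the brightest, the sets of the main run staying at 1.18 to 1.19 and -1.32 to -1.18. So did the values of Elavl2 without wild-type E10 replicate 1 (-1.47 for stage, -0.92 at E10, -0.30 over both stages), where its main set was at -2.04, -1.63 and -0.72.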

Other observations

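The tests in this part were planned, and the sex-linked values are given without a test.

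Single members of further lists passed limma in labelled-null against wild-type vesicles over both stages when adjusted over the list alone, and none of them over all genes. Lower were Pax8, an early otic transcription factor gene (-0.93, SE 0.16), Sox2 of the prosensory domain (-0.53, SE 0.11), the hedgehog co-receptor gene Gas1 (-0.48, SE 0.11), the receptor gene Ret of the neural crest list (-0.47, SE 0.11) and the antiviral gene Oas1a (-0.86, SE 0.21). Higher was Aldh1a3, a retinaldehyde dehydrogenase gene (1.29, SE 0.29). Of 20 tested neighbours of Dlx5 on its chromosome, Asns (0.50, SE 0.12) was higher and Rpa3 (-0.84, SE 0.15) lower, and the list did not pass (camera adjusted p = 0.0603). In wild-type vesicles 3 of 18 periotic mesenchyme genes rose from E10 to E10.5 over all genes in limma, the proteoglycan genes Lum (2.48, SE 0.41) and Dcn (1.52, SE 0.17) and the collagen gene Col1a1 (1.17, SE 0.22). Adjusted over the list alone 6 rose, and the list did not pass (median 0.41, camera adjusted p = 0.0758).

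The lists of the otic placode, ventral otocyst, hair cells, Wnt, FGF, Notch and hedgehog genes, hindbrain, neural crest, surface ectoderm, macrophages, p53 targets, immediate early genes, hypoxia and glycolysis, and bone differentiation passed camera in none of the 6 comparisons. Their smallest adjusted p was 0.0808.

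Xist, expressed from the inactive X chromosome, was at 5.07 and 9.72 in wild-type and 4.98 and 9.36 in labelled-null arrays at E10, and at 9.17 and 9.01 in wild-type and 8.91 and 9.01 in labelled-null arrays at E10.5. The Y-linked Eif2s3y was at 7.04 and 3.96 in wild-type and 6.50 and 6.17 in labelled-null arrays at E10, and at 3.21 and 3.45 in wild-type and 4.82 and 5.04 in labelled-null arrays at E10.5. In 2B1 cells Xist was at 4.04 and 3.99 after Dlx5 transfection and 4.08 and 3.37 with the empty vector, while Eif2s3y was at 8.06 and 8.21 and at 7.70 and 7.61 in the same order.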
